A study of Mus musculus with 14 samples.

How the data were processed

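Liver total RNA of 14 male mice was labelled with biotin and hybridized to Illumina bead arrays, per the labels, with 7 Gas7 transgenic and 7 FVB wild-type mice. The deposited values are intensity values on a linear scale, made with BeadStudio 1.5.1.3 per the submitters' processing notes. They are background-subtracted, since between 32.1% and 36.4% of the values of an array lie below 0. The step that made these values from the scanner output is not given in the sources used here. A further deposited table of signals per array was not used, because its 112 columns carry names that match no label of any sample. Slides and detection scores were therefore not used here. Groups come from the labels of each sample, and replicate numbers were given in accession order and pair no samples.

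No table in use pairs probes with genes. Zero-padded numbers of 11000 or more inside probe identifiers were looked up as gene numbers in a table of RefSeq genes (assembly GRCm38.p6, used for names only, with no coordinates). Of 9523 such identifiers, 93.3% held a number of the table, against 48.6% after 1 was added to each number. Unpadded numbers matched in 10.7% of cases and in 10.3% after adding 1, and were left unnamed. The 159 pairs of bright probes that share a gene number had a median correlation of 0.540 across the 14 arrays, against 0.062 for the same probes paired at random. Probes so named for secreted hepatocyte proteins had a median intensity of 11230, and those named for pancreatic enzymes 2.35. In all, 8896 of 24048 probes were named, for 7413 genes, and 15152 were left unnamed. The names are those of the current table and rest on this match.

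Background was modelled with normexp on all probes of an array (offset 16), followed by quantile normalization and log2. The plan had been to infer negative controls from detection scores. Without those scores normexp was run without controls, and the filter on detection was replaced. Values below 0 were mirrored at 0 on each array to describe unlit probes, and probes above the 95th percentile of that noise on at least 7 of the 14 arrays were kept. Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p below 0.05) on all 14 arrays without covariates, 1 probe at a time. Differences are transgenic minus wild type, and the log2 differences of dim probes are compressed by the offset.

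Gene lists were written before the data were examined, as were the main test, the rule for naming genes and the alternatives, except those said below to be added later and the fasting-induced, histone and immunoglobulin sets of the closing observations, which were chosen after the main result was seen. Of 39 lists, 26 had at least 5 measured genes. They were tested with camera (preset correlation of 0.01, the brightest probe of each gene, Benjamini-Hochberg over the lists). The estimated correlation, the rotation test fry and an exact permutation test of the mean over a list's genes per array (all 3432 ways to choose 7 of 14 arrays, two-sided) were set beside it. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. The standard error of a list mean is taken over arrays.

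Named genes were to be the transgene, then up to 10 genes per direction past the threshold. Where fewer passed, genes of the smallest unadjusted p filled each direction up to 5, passing over predicted genes and clone names. Up to 4 members of a called list and 1 or 2 of any other list, by smallest p, were named as values. A list with an unadjusted camera p below 0.1 gave 2 members and other lists gave 1, a choice made after the values were seen. Members named outside this rule (Fasn and Dcn) were chosen after their values were seen. A member that the rule would name is not reported here, though it counts in its list and among the probes followed over the alternatives.

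The tests were run first on simulated data with the means and spreads of the real probes. Noise was drawn independently for each probe, and all changed probes were planted at once. Of 50 probes each changed by 1.41-fold, 2-fold, 2.83-fold and 4-fold among 9703, the transgenic against wild-type fit recovered 60%, 94%, 96% and 100%, with 9 false calls among the unchanged probes. Alternatives were other background and scaling steps, other filters on dim probes, array weights, a variance trend with a robust prior, the number in a sample's title as a random block, its last letter as a covariate, and each of the 14 arrays left out in turn. A filter on mean intensity above 100, a fit on named genes alone, the exact test of list means and the estimated correlation with each array left out were added after the data were seen.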

Results

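The liver transcriptomes of 14 male mice were measured on Illumina bead arrays, with 1 array per mouse. Of these mice, 7 carried a Gas7 transgene and 7 were wild-type animals of FVB, an inbred laboratory strain. All were 23 weeks old and had been switched from chow with 4% fat to chow with 6% fat at week 11. Gas7 (growth arrest-specific 7) encodes an actin-binding protein first described in growth-arrested cells, and the gene has been studied as a candidate for body fat in mouse crosses. The comparison asks which liver transcripts differ in males that carry the transgene. The labels describe separate mice, so p-values measure the spread between animals of a group, and the number of arrays limits the precision. The number in a sample's title recurs within each group and is mostly not shared between groups, and its meaning is not stated. If it marks a shared origin, animals of a group are not all independent, and that origin can hardly be separated from the transgene. As a random block this number gave a correlation of 0.029 between arrays, 1 value for all tested probes, which does not exclude a shared origin. Number 1 alone occurs in both groups, on transgenic replicate 1 and wild-type replicate 1. These arrays had the highest means of growth hormone and IGF axis genes (11.165 and 11.23, next 10.92) and of male-biased genes (12.30 and 12.27, next 12.14). Their female-biased means were the lowest (9.40 and 9.41, next 9.55). These lists were picked after their values were seen.

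Median deposited intensity ranged from 10.7 to 22.5 per array, and between 9123 and 10536 of the 24048 probes stood above the noise of unlit probes. A total of 9703 probes did so on at least 7 arrays and were tested, of which 3885 were named, for 3584 genes. Names rest on reading the number inside a probe identifier as a gene number, a match that no source states and that was tested as described under the processing. No probe was named for Gas7 by this route, so the transgene itself was not analysed here and the labels have no check from its level. One array stood apart from the rest. Wild-type replicate 7 had a median Pearson correlation of 0.930 with the other arrays, where the other arrays had 0.975 to 0.987, and an 18S rRNA intensity of 156.6 against 3461 to 7925 elsewhere.

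**Figure D1:**
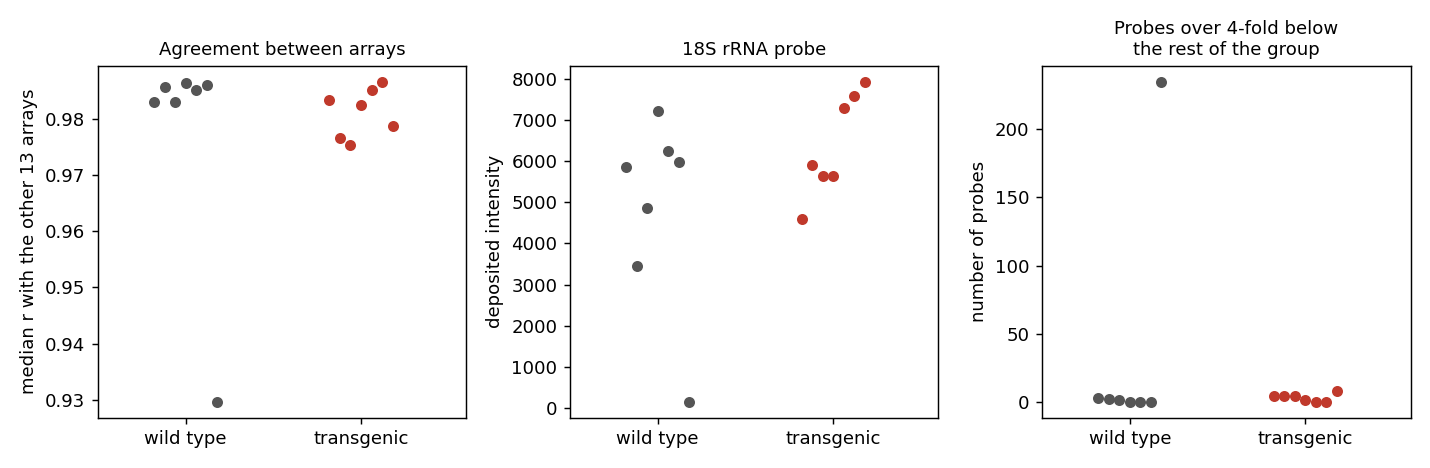
Agreement, 18S rRNA and low probes per array, with 1 point per mouse and replicates 1 to 7 from left to right in each group. The left panel gives the median Pearson correlation of normalized log2 values with the other arrays, the middle panel the deposited intensity of the 18S rRNA probe, and the right panel the number of probes more than 4-fold below the mean of the other 6 arrays of the same group. Wild-type replicate 7 lies at 0.930, 156.6 and 235.

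No single gene passed the adjusted test between the groups, and 4 small sets of genes passed 1 of the 4 list tests run. Fatty acid synthesis enzymes and genes of stellate cells and their matrix had a lower mean in transgenic liver, by -0.36 and -0.27 on the log2 scale, and heat shock proteins a higher one, by 0.23. Acute-phase genes were also called higher, at 0.31, with 1 transgenic mouse behind most of that value. These 4 of 26 gene lists passed the planned test, limma's camera with its preset correlation, and 0 of them passed when the correlation between genes was estimated from the data, by fry or by the exact permutation test. Of 100 splits of the arrays into 7 and 7, the real one included, 40 gave at least 4 called lists.

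Of the 9703 probes, 0 were higher and 0 lower in transgenic liver by limma's moderated test at a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.491. At an unadjusted p under 0.05 there were 656 probes, where chance alone would give 485. Of these, 214 were higher and 442 lower in transgenic liver. That split depended on the scaling, with 58 higher and 363 lower after scaling by the median, and 465 higher and 181 lower in the deposited values without further normalization. The median standard error of a log2 difference was 0.118. In simulated arrays with the spread of these 14, the same test recovered 60% of 50 probes changed by 1.41-fold and 94% of 50 probes changed 2-fold. Those probes were planted together with others changed 2.83-fold and 4-fold, which eases the adjusted threshold. The rates therefore do not tell how many changes of these sizes would be found if few probes changed.

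The named genes with the smallest p are given as values, since each had an adjusted p of 0.507 or 0.614 by limma. Among those with the higher mean in transgenic liver, H4c8, a histone H4 gene, differed by 0.62 ± 0.13 (log2 difference ± SE, n = 7 per group, as for the values that follow). Pck1, which encodes the cytosolic enzyme that commits oxaloacetate to gluconeogenesis, differed by 0.72 ± 0.20, or 1.65-fold, with 10.28 ± 0.39 (SD) in wild type and 10.99 ± 0.45 in transgenic liver and all 7 transgenic arrays above the wild-type mean. Map1lc3b, the autophagosome protein LC3B, differed by 0.38 ± 0.10, and the argonaute gene Ago2 by 0.40 ± 0.12. Kyat3, a kynurenine aminotransferase, differed by 0.86 ± 0.23 and stood above the noise on 2 of 7 wild-type and 6 of 7 transgenic arrays, and Ago2 did so on 3 of 7 wild-type arrays. On the other side, Sipa1l2 (above the noise on 3 of 7 transgenic arrays) differed by -0.58 ± 0.12 and the collagen VI gene Col6a1 by -0.43 ± 0.10. Pfkm, the muscle-type phosphofructokinase, differed by -0.31 ± 0.08, Gpr146, an orphan receptor, by -0.38 ± 0.10, and Dennd3 by -0.35 ± 0.09. Leaving out wild-type replicate 7 kept all of these signs, with 0.72 for Pck1 and 0.57 for H4c8.

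The fatty acid synthesis list had 6 of its 21 genes measured, and all 6 had a lower mean in transgenic liver. The list averaged 11.02 ± 0.28 (SD, n = 7) in wild type and 10.66 ± 0.22 in transgenic liver, a log2 difference of -0.36 ± 0.13 (SE), and all 7 transgenic arrays lay below the wild-type mean. Acaca, the acetyl-CoA carboxylase that makes malonyl-CoA, differed by -0.50 ± 0.15, from 11.48 ± 0.25 (SD) in wild type to 10.98 ± 0.33. Elovl6, which elongates saturated fatty acids, differed by -0.54 ± 0.19. Acly and Acss2, which supply cytosolic acetyl-CoA from citrate and from acetate, differed by -0.38 ± 0.17 and -0.37 ± 0.18, and the synthase Fasn by -0.23. The list had an adjusted p of 0.00127 by camera with the preset correlation and an adjusted p of 0.308 with an estimated correlation. An exact permutation test of the array means over all 3432 splits gave p = 0.0192, and p = 0.116 after adjustment over the 26 lists. Of its members 2 passed when adjusted over the list alone, Acaca and Elovl6, and 0 passed over all probes tested. Wild-type replicate 7 had the highest mean of this list, and without it the difference was -0.30. Transgenic replicate 2 had the lowest, 10.23, and without it the difference was -0.29. The groups overlapped, with wild-type replicates 1 and 4, at 10.62 and 10.68, inside the transgenic range of 10.23 to 10.89.

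The stellate cell and matrix list had 7 of its 34 genes measured, of which 6 had a lower mean in transgenic liver. It averaged 9.16 ± 0.16 (SD, n = 7) in wild type and 8.89 ± 0.15 in transgenic liver, a log2 difference of -0.27 ± 0.08 (SE), with all 7 transgenic arrays below the wild-type mean. Wild-type replicates 4 and 5, at 9.07 and 8.96, lay inside the transgenic range of 8.67 to 9.075. Besides Col6a1, the collagen genes Col5a1 and Col6a3 differed by -0.37 ± 0.13 and -0.37 ± 0.17. Lrat, the enzyme that esterifies retinol for storage in stellate cells, differed by -0.41 ± 0.16. Dcn, which encodes decorin, was the 1 member with a higher mean, at 0.03. The adjusted p was 0.00127 by camera, with an adjusted p of 0.239 with an estimated correlation, and the exact permutation test gave p = 0.00583, or 0.0758 after adjustment. Adjusted over the list alone, 3 members passed (Col6a1, Col5a1 and Lrat), against 0 over all probes tested. Without wild-type replicate 7 the difference was -0.25. Markers of the other non-parenchymal cells had mean differences of -0.13 ± 0.14 (SE) for the 7 endothelial genes, with the smallest p for Egfl7 at -0.32 ± 0.13, and 0.14 ± 0.21 for the 7 Kupffer cell genes, with the smallest p for C1qa at 0.52 ± 0.40 (0.13 without wild-type replicate 7), and neither list was called (adjusted p = 0.343 and 0.385 by camera). With 1 array left out at a time, the endothelial mean ran from -0.19 without transgenic replicate 1 to -0.03 without transgenic replicate 3, the Kupffer mean from 0.05 without transgenic replicate 4 to 0.24 without transgenic replicate 3, and the matrix list from -0.31 without wild-type replicate 5 to -0.23 without wild-type replicate 6.

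The heat shock list had 7 of its 14 genes measured, of which 6 had a higher mean in transgenic liver. The list averaged 11.29 ± 0.17 (SD, n = 7) in wild type and 11.51 ± 0.10 in transgenic liver, a log2 difference of 0.23 ± 0.07 (SE), and all 7 transgenic arrays lay above the wild-type mean. The groups overlapped, however. Wild-type replicates 2, 3 and 7 lay at 11.08 to 11.14 and the other wild-type arrays at 11.365 to 11.516, against 11.371 to 11.651 in transgenic mice. Hspb1, a small heat shock protein, differed by 0.51 ± 0.21, and Hspe1, the mitochondrial co-chaperonin, by 0.26 ± 0.11. Hsf1, the transcription factor of the heat shock response, differed by 0.22 ± 0.09. The constitutive chaperone Hspa8 differed by 0.17 ± 0.08, and by 0.28 ± 0.10 on its other probe. The adjusted p was 0.00117 by camera, with an adjusted p of 0.235 with an estimated correlation, and the exact permutation test gave p = 0.00874, or 0.0758 after adjustment. No member passed either when adjusted over the list alone (smallest 0.0734) or over all probes. Without wild-type replicate 7 the difference was 0.20.

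**Figure D2:**
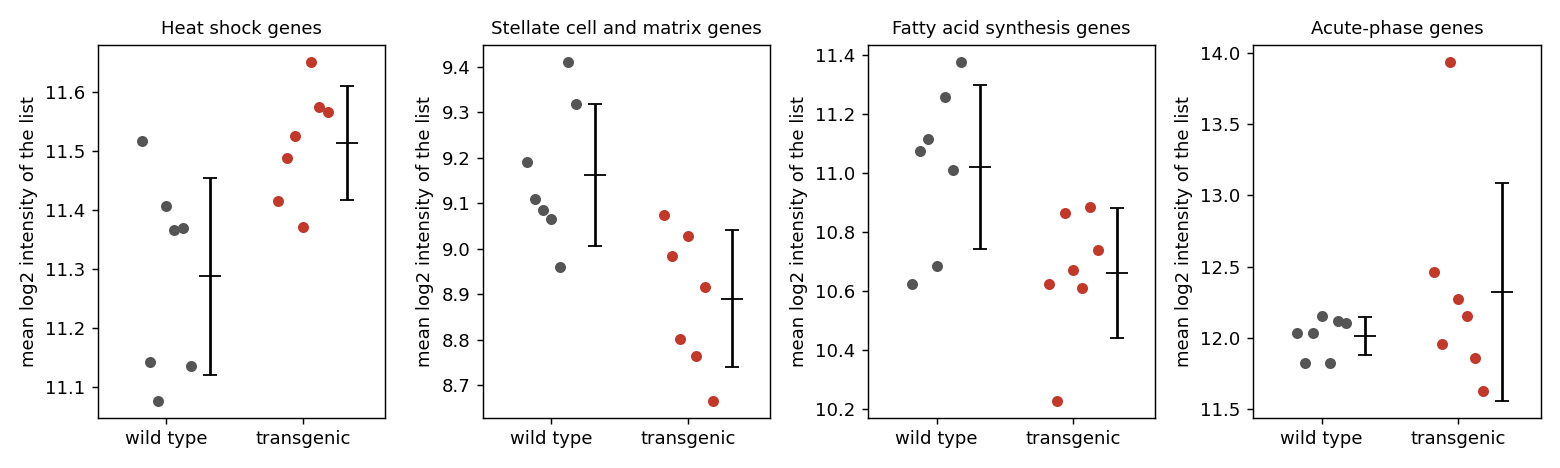
Mean normalized log2 intensity per array of the 4 called gene lists, with 1 point per mouse, replicates 1 to 7 from left to right in each group, and the group mean ± SD (n = 7) as bars. All 7 transgenic points lie above the wild-type mean for heat shock genes and below it for matrix and fatty acid synthesis genes. For acute-phase genes transgenic replicate 3 lies alone at 13.94.

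The acute-phase list holds plasma proteins that hepatocytes make during inflammation. It had 8 of its 28 genes measured, 7 of them with a higher mean in transgenic liver. It averaged 12.02 ± 0.14 (SD, n = 7) in wild type and 12.32 ± 0.76 in transgenic liver, a log2 difference of 0.31 ± 0.29 (SE), and 4 of 7 transgenic arrays lay above the wild-type mean. Saa1, a serum amyloid A gene, differed by 1.03 ± 0.70 with a transgenic SD of 1.92, Orm1 by 0.27 ± 0.18, Cp, which encodes ceruloplasmin, by 0.27 ± 0.18, and Serpina3k by 0.15 ± 0.10. No member passed when adjusted over the list alone (smallest 0.357). Without transgenic replicate 3 Saa1 differed by 0.45, Orm1 by 0.11 and Cp by 0.165, and without wild-type replicate 3 Cp differed by 0.158. The adjusted p was 0.0487 by camera, with an adjusted p of 0.715 with an estimated correlation, and the exact permutation test gave p = 0.379. Without transgenic replicate 3 the difference was 0.041 and the call was lost (adjusted p = 0.491). The call was also lost without transgenic replicate 1 or 4 or wild-type replicate 1, 2, 3 or 5, at differences of 0.28 to 0.32 and adjusted p from 0.0542 to 0.0902.

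The other 22 lists were not called, with adjusted p from 0.0562 to 0.990 by camera, and the members named here did not pass the adjusted test over all probes. With an estimated correlation 0 of the 26 lists passed, whichever array was left out, and 0 passed by the exact permutation test. Before adjustment the exact permutation p was 0.00524 for secreted plasma proteins, the smallest of the 26 lists. It was 0.0268 for the p53 list, 0.0321 for lipoproteins and 0.0239 for the citric acid cycle. By camera, growth arrest genes of the p53 pathway came closest. Their 5 measured members averaged 0.53 ± 0.23 higher, mostly through Cdkn1a, the cyclin-dependent kinase inhibitor p21, which differed by 1.87 ± 0.65, with 6.52 ± 0.53 (SD) in wild type and 8.40 ± 1.91 in transgenic liver. Cdkn1a stood above the noise on 2 of 7 wild-type and 6 of 7 transgenic arrays, so its difference, and the part of the list mean that rests on it, is taken mostly against values within the noise and its size is not well measured. It reached 11.79 in transgenic replicate 2, and the difference was 1.31 without that array. The stress-induced cytokine Gdf15 differed by 0.60 ± 0.41, and by 0.30 without transgenic replicate 2. The list mean ran from 0.36 without transgenic replicate 2 to 0.62 without transgenic replicate 7. Without wild-type replicate 7 this list passed, with an adjusted p of 0.00478 by camera and an adjusted p of 0.170 with an estimated correlation. It also passed by camera without wild-type replicate 4 or transgenic replicate 3, 5, 6 or 7, with adjusted p from 0.0251 to 0.0471.

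**Figure D3:**
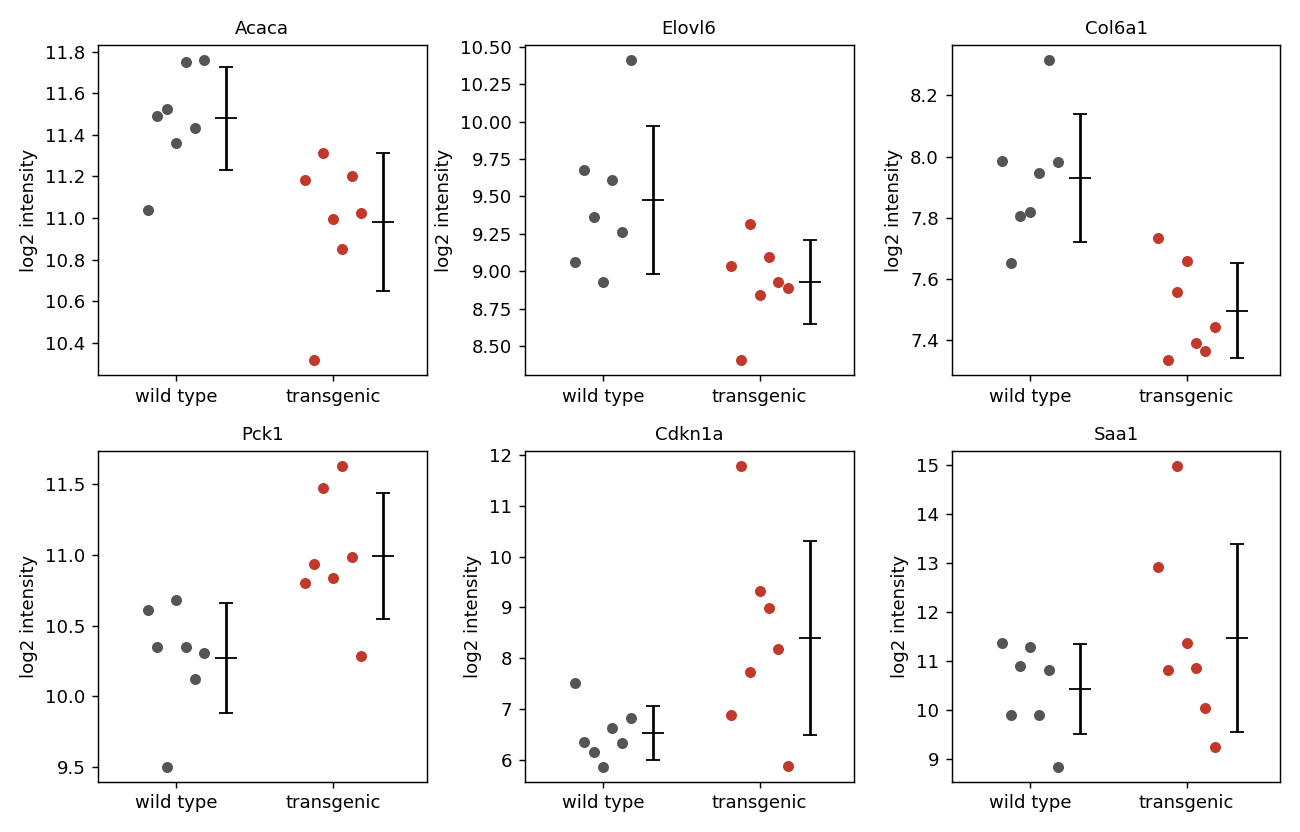
Normalized log2 intensity per array of Acaca, Elovl6, Col6a1, Pck1, Cdkn1a and Saa1, with 1 point per mouse, replicates 1 to 7 from left to right in each group, and the group mean ± SD (n = 7) as bars. Cdkn1a spans 5.88 to 11.79 in transgenic mice and 5.87 to 7.51 in wild type.

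Among genes of lipid transport and energy metabolism, the 10 lipoprotein genes averaged 0.20 ± 0.12 higher (adjusted p = 0.0656 by camera), with the HDL receptor Scarb1 at 0.32 ± 0.11 and Apoa4 at 0.90 ± 0.44. That mean was 0.084 without wild-type replicate 7, whose Apoa4 value lay far below those of the other arrays, and Apoa4 then differed by 0.42. The list passed by camera without transgenic replicate 3 or 5 or wild-type replicate 1, 3 or 4, at means of 0.20 to 0.23 and adjusted p from 0.0358 to 0.0457, but at an adjusted p of 0.501 or more with an estimated correlation. The 11 cholesterol synthesis genes averaged -0.18 ± 0.16, with Fdps at -0.54 ± 0.27 (-0.33 without transgenic replicate 2) and Acat2 at -0.34 ± 0.16 (-0.21 without wild-type replicate 7). Their mean was -0.068 without transgenic replicate 2, and the list passed by camera without transgenic replicate 3 (-0.27, adjusted p = 0.00984) or wild-type replicate 4 (-0.23, adjusted p = 0.0471), but at an adjusted p of 0.584 and 0.741 with an estimated correlation. Fatty acid oxidation genes averaged -0.01 ± 0.08 over 11 genes, although camera ranked them upward and their median was 0.05, and Acot3 differed by -0.63 ± 0.26. Leaving out single arrays turned that mean, from -0.06 without transgenic replicate 2 to 0.02 without transgenic replicate 4. Oxidative phosphorylation (29 genes) averaged -0.02 ± 0.05, with the smallest p for Atp5g1 at -0.17 ± 0.10 (-0.11 without transgenic replicate 3), and its mean ran from -0.05 without transgenic replicate 7 to 0.006 without transgenic replicate 3. The glycolysis and gluconeogenesis list (15 genes) averaged 0.04 ± 0.03 and the citric acid cycle list (10 genes) 0.08 ± 0.03, both holding Pck1 as the 1 member that passed when adjusted over the list alone. The median was -0.03 in each of these lists, and their means ran from 0.03 without wild-type replicate 3 to 0.06 without transgenic replicate 7 and from 0.06 without wild-type replicate 3 to 0.09 without wild-type replicate 1. Growth hormone and IGF axis genes (7) averaged 0.06 ± 0.17, although their median was -0.02 and camera ranked them downward, and Jak2 differed by -0.32 ± 0.11. Their mean ran from -0.02 without transgenic replicate 1 to 0.16 without wild-type replicate 1.

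Plasma protein, amino acid, xenobiotic, sex-biased and antioxidant genes showed no called difference. The 7 genes of secreted plasma proteins averaged 0.18 ± 0.10 higher (adjusted p = 0.140 by camera, exact permutation p = 0.00524, or 0.0758 after adjustment), with all 7 transgenic arrays above the wild-type mean, Serpina1a at 0.23 ± 0.10 and the transferrin gene Trf at 0.83 ± 0.58. Without wild-type replicate 7 the list mean was 0.083, Serpina1a differed by 0.14 and Trf by 0.19. Amino acid and urea cycle genes (5) averaged 0.19 ± 0.15, with the smallest p for Bhmt at 0.67 ± 0.42, and without transgenic replicate 3 the list mean was 0.11 and Bhmt differed by 0.34 (highest list mean 0.26, without wild-type replicate 7). Xenobiotic metabolism genes (12) averaged 0.09 ± 0.16, with the smallest p for Por, the cytochrome P450 reductase, at 0.44 ± 0.19, and their mean ran from 0.02 without wild-type replicate 7 to 0.16 without transgenic replicate 1. Male-biased liver genes (14) averaged 0.11 ± 0.11, with the smallest p for Cyp4a12a, which ran against that mean at -0.18 ± 0.09, and female-biased genes (6) -0.11 ± 0.22. The male-biased mean ran from 0.07 without transgenic replicate 1 to 0.17 without wild-type replicate 1, and the female-biased mean from -0.22 without wild-type replicate 1 to -0.02 without transgenic replicate 1. NRF2 targets and antioxidant genes (11) averaged -0.10 ± 0.08, with the smallest p for Pgd at -0.29 ± 0.13, and their mean ran from -0.15 without wild-type replicate 1 to -0.06 without transgenic replicate 2.

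Immune and housekeeping lists were not called either. Interferon response genes (11) averaged -0.21 ± 0.16 (adjusted p = 0.140 by camera), with the interferon-induced GTPase Igtp at -0.74 ± 0.29. Igtp was at 11.59, 12.20 and 11.47 in wild-type replicates 3, 6 and 7 and at 10.05 to 10.45 in the other wild-type arrays. The interferon mean was -0.12 without wild-type replicate 6, and the list passed by camera without wild-type replicate 1 (-0.30, adjusted p = 0.0184) or 4 (-0.26, adjusted p = 0.0453), but at an adjusted p of 0.501 and 0.697 with an estimated correlation. MHC class II genes (6) averaged -0.24 ± 0.32, with the smallest p for H2-DMb1 at -0.42 ± 0.27, and their mean ran from -0.36 without wild-type replicate 1 to -0.05 without transgenic replicate 3. Cell cycle genes (8) averaged -0.08 ± 0.08 with a median of 0.002, with the smallest p for the mitotic kinase Plk1 at -0.31 ± 0.13 (above the noise on 1 of 7 transgenic arrays), and their mean ran from -0.11 without transgenic replicate 7 to -0.04 without wild-type replicate 5. Actin cytoskeleton genes (27), of interest because Gas7 binds actin, averaged 0.03 ± 0.05 with a median of -0.004, with the smallest p for Cnn3, which encodes calponin 3 and ran against that mean at -0.29 ± 0.10. Their mean ran from -0.01 without wild-type replicate 7, which turned its sign, to 0.06 without transgenic replicate 3. Proteasome genes (12) averaged 0.04 ± 0.05, with the smallest p for Psmb5 at 0.31 ± 0.13, and ribosomal protein genes (37) 0.01 ± 0.03, with the smallest p for Rpl30 at 0.21 ± 0.12. The proteasome mean ran from 0.02 without wild-type replicate 4 to 0.07 without transgenic replicate 2, and the ribosomal mean from -0.005 without wild-type replicate 7 to 0.02 without wild-type replicate 1.

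**Figure D4:**
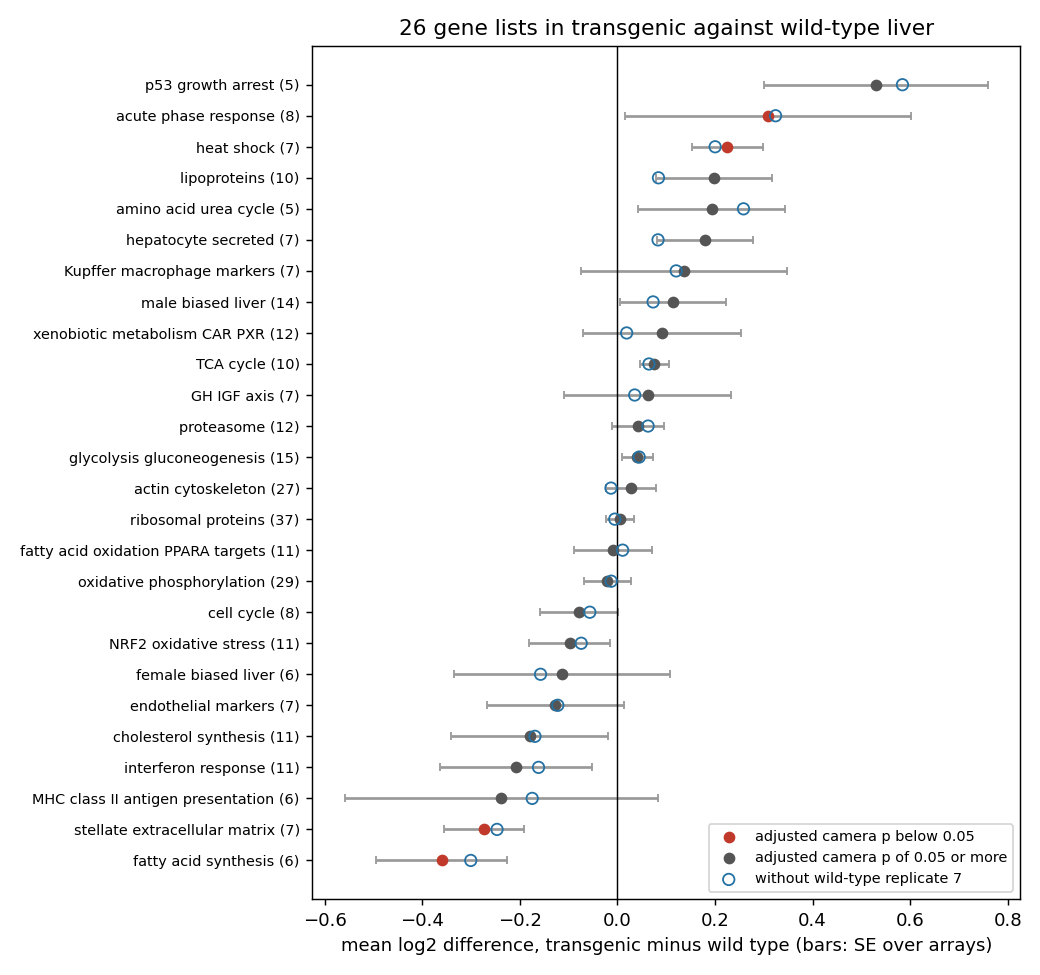
Mean log2 difference, transgenic minus wild type, of each of the 26 gene lists, with bars for the SE over the 14 arrays and the number of measured genes in parentheses after each name. Filled red points mark the 4 lists with an adjusted camera p below 0.05 at the preset correlation, and open circles give the value without wild-type replicate 7. Fatty acid synthesis lies lowest at -0.36.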

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

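The tests of wild-type replicate 7 for overall brightness and for another tissue, the test of each list without that array, the comparison with other non-parenchymal cells and the split count of probes past the threshold were chosen after the result was seen. So were the condition that a list without that array stay 2 standard errors from 0, the condition that the comparison with other cells hold without it, and that comparison with each other array left out. In 160 groups of 7 values, 18 held a value far from the other 6 by Dixon's test, where chance gives about 1 in 20, or 8. Of these 18, 10 were on wild-type replicate 7.

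Wild-type replicate 7 was the lowest of its group in the 75th percentile of intensity (96.8, next 132.55) and in the median correlation with other arrays (0.930, next 0.983). It was also lowest in the list means of secreted hepatocyte proteins (12.45, next 13.07), lipoproteins (12.03, next 12.71) and the actin cytoskeleton (9.04, next 9.28). Single genes lowest on this array were Trf (8.87, next 12.90), Apoa4 (6.86, next 10.02), C1qa (6.83, next 9.03) and Serpina1a (12.90, next 13.40), whereas Acat2 was highest there (11.33, next 10.70). The array held 235 probes more than 4-fold below the mean of the other 6 wild-type arrays and 0 more than 4-fold above, against 0 to 8 probes that far below on the other 13 arrays. The median deviation over all probes was 0.12. Lower overall brightness is argued against, since normalization leaves no such one-sided loss (235 probes below per probe above, counting 0 above as 1), and so is another tissue, since the secreted hepatocyte genes deviated by a median of -0.092. Failure of single probes stays open. Of 13 genes with several probes and 1 of them more than 4-fold below, 3 had the next probe more than 2-fold below. That is 23.1% (exact 95% interval 5.04% to 53.8%), under the bound set for such failure, but the next probe being low in most genes is not excluded. Several histone genes were low together on this array, with H2bc14 at -4.70, H2ac19 at -4.14 and H2bc13 at -3.73 from the other wild-type arrays. Others were not, such as H2bc12 at -0.10, and the median over histone genes was -0.31. Low values shared by related genes were not part of that test. No biological explanation was tested.

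The lower fatty acid synthesis genes of transgenic liver are not accounted for by wild-type replicate 7 alone, with a difference of -0.30 ± 0.13 (SE) without that array. Of 100 splits of the 14 arrays, the real one included, 3 gave a difference as large (real 0.36, highest other 0.41). For a list fixed alone that lies below the 0.05 level. This list, however, was picked from 26 after it was called on these arrays. Its exact permutation p adjusted over the 26 lists was 0.116, so chance is not excluded. A difference in feeding before sampling may contribute, but the test could not decide: without Pck1, whose value was already known, the 3 measured fasting-induced genes (2 of them also in the fatty acid oxidation list) differed by 0.04 ± 0.13, with a 95% interval of -0.24 to 0.32 (exact permutation p = 0.773, and p = 0.149 with Pck1). Within the 7 transgenic arrays these genes correlated with the fatty acid synthesis mean at r = -0.63 (exact permutation p = 0.140, adjusted 0.487) and rho = -0.11 (p = 0.840, adjusted 0.840), and within the 7 wild-type arrays at r = -0.51 (exact permutation p = 0.243, adjusted 0.487) and rho = -0.39 (p = 0.396, adjusted 0.528). Over the 4 tests none passed. Without the 2 arrays of each group farthest from its median for the fasting-induced genes, r was 0.88 and 0.85. The negative r thus rests on those arrays. They are also the arrays in which a feeding difference would show most, so leaving them out does not argue against one. An effect of the transgene stays open too.

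The lower stellate cell and matrix genes are not accounted for by wild-type replicate 7 alone, with a difference of -0.25 ± 0.08 (SE) without that array. Of 100 splits, the real one included, 3 gave a difference as large (real 0.27, highest other 0.29). This list too was picked from 26 after it was called on these arrays. Its exact permutation p adjusted over the 26 lists was 0.0758, so chance is not excluded. Fewer non-parenchymal cells of every type cannot be told apart from a change in these genes. The Kupffer list mean lay above the matrix list mean by 0.41 ± 0.18 (SE), which passes the bound of 2 standard errors first set. Without wild-type replicate 7 the gap was 0.37 ± 0.19, which does not pass that bound. With each of the 14 arrays left out in turn, a step added later, the gap ran from 0.35 ± 0.18 to 0.53 ± 0.14 and passed in 9 cases. The lowest value, without transgenic replicate 4, does not pass, and the highest was without wild-type replicate 3 (0.50 ± 0.16 without transgenic replicate 3). The endothelial mean lay above the matrix mean by 0.15 ± 0.13, and by 0.23 ± 0.09 without transgenic replicate 3, the 1 array without which it passed. An effect of the transgene on stellate cells stays open as well.

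On transgenic replicate 3 the acute-phase list mean was the highest of its group (13.94, next 12.46), with Orm1 at 15.17 (next 14.34), Psmb5 highest at 9.68 (next 9.20) and the actin cytoskeleton list mean lowest at 9.14 (next 9.32). Transgenic replicate 2 was lowest in the fatty acid synthesis list mean (10.23, next 10.61) and in Acat2 (9.67, next 10.20). The citric acid cycle list mean was highest on transgenic replicate 5 (11.28, next 11.22). Plk1 was lowest on wild-type replicate 1 (6.37, next 6.65).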

How the results depend on the processing

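The slide as a block and all fits for Gas7 were not run, and no paired analysis was possible because the replicate numbers follow accession order. The exact test, the mean intensity filter and the fit on named genes were chosen after seeing the data. Every setting kept the sign of the 49 named probes (1215 values), and no setting called a probe except leaving out wild-type replicate 4, so the count ran from 0 to 1 over the arrays left out. That 1 probe, not named here, differed by -0.66 ± 0.09 (SE; limma adjusted p = 0.0263, against -0.56 and 0.507 with all arrays). The named genes alone gave 0 of 3584.

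Of 26 lists, 4 were called, against 7 with median scaling, 9 in the deposited values not normalized again (where the median probe differed by 0.097), and 0 with an estimated correlation, with fry and with the exact permutation test. Leaving out arrays gave 3 to 8, the 8 without wild-type replicate 4 adding lipoproteins, p53, cholesterol synthesis and interferon response. The fatty acid synthesis (-0.36), matrix (-0.27) and heat shock (0.23) calls held under all 25 settings of the values, filters and arrays, and were lost under the estimated correlation, fry and the exact test, where their p before adjustment were 0.00453 to 0.0356, and did not pass after adjustment over the 26 lists. The acute-phase call held under 13 of the 25. It was lost without background correction (0.307), without a filter (0.309), with array weights (0.205), with the variance trend (0.309), with the title number as a random block (0.311), with the mean of a gene's probes, the estimated correlation, fry and the exact test (0.309 each), and over the arrays left out it ran from 0.041, without transgenic replicate 3, to 0.426. Apart from these arrays and tests the cause was not tested. The p53 list was called under 8 settings, lipoproteins under 7, cholesterol synthesis and interferon response under 3 each, and secreted hepatocyte proteins, proteasome and ribosomal proteins under 1 each. Signal over background limits the 14345 probes that were not tested.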

Other observations

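Histone genes were looked at because H4c8 headed the list of higher genes, and this test was chosen after that result was seen. Of 31 other measured histone genes, 26 had a higher mean in transgenic liver, with an average log2 difference of 0.29 ± 0.15 (SE over arrays). H2bc12 differed by 0.33 ± 0.10, H4c11 by 0.37 ± 0.14 and H4c12 by 0.33 ± 0.13, named after their values were seen. An exact permutation test of the array means gave p = 0.0105. Part of the size came from wild-type replicate 7, which the count of 26 includes. On that array the histone genes, H4c8 among them, deviated from the other wild-type arrays by a median of -0.31, with H2bc14 lowest at -4.70. Without this array the average was 0.14 ± 0.05 (exact permutation p = 0.0221). Over all settings run it stayed above 0, from 0.14 to 0.65, the highest in the deposited values not normalized again. Many histone transcripts lack a poly(A) tail and histone genes resemble each other in sequence, so a difference in labelling or shared signal between probes may contribute and stays open. Since the set was chosen for H4c8, its p is not independent of that gene. The median correlation of the other histone genes with H4c8 within groups was 0.27, just under a bound that was added after the p was seen and that decides nothing here.

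Immunoglobulin segment probes were examined for a difference in plasma or B cells. The 23 detected probes averaged 0.04 ± 0.03 (SE) higher in transgenic liver, with 13 of them higher, and the exact permutation test gave p = 0.246, which leaves a small difference open. Among lists with fewer than 5 measured genes, which were not tested as lists, the immunoglobulin kappa constant gene Igkc differed by 0.72 ± 0.35 and the lipid droplet gene Plin4 by 0.53 ± 0.32. The circadian genes Rora and Clock differed by 0.37 ± 0.21 and 0.26 ± 0.15. Stx8, the 1 measured gene of those listed near Gas7, differed by -0.02 ± 0.09. These 5 genes were chosen after their values were seen, and none passed the adjusted limma test.

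The count of probes at an unadjusted p under 0.05 and the count of called lists did not exclude chance. For probes past the adjusted threshold the splits decide nothing, since the real count is 0 and all 100 splits of the 14 arrays reach it, and 2 of the 99 other splits called any probe, the highest 50. At an unadjusted p under 0.05, 17 of 100 splits reached the real 656 probes (highest other 1151, median of the others 416). For gene lists, 40 of 100 splits reached the real 4 (highest other 9, median of the others 3), and 78 of the 99 other splits called at least 1. The split of Cdkn1a within the transgenic group was wide, with 11.79 in replicate 2, 9.32 in replicate 4 and 8.99 in replicate 5, against 5.88 in replicate 7.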
